A study of Mus musculus with 22 samples.

How the data were processed

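RNA was measured in the hypothalamus of C57BL/6J mice by sequencing of polyadenylated RNA. PWScrm+/p− mice inherit a deletion of the Snord116 small nucleolar RNA genes from the father and are called mutant here, and PWScrm+/p+ mice without it are called control. The 22 libraries come from 22 separate mice, so no test was paired. Each genotype was sampled at ZT0 (lights on), at ZT6 and at ZT6 after 6 h of sleep deprivation (SD). The labels give no sex.

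Per the labels, total RNA was taken up in Trizol, TruSeq polyA libraries were sequenced on a NovaSeq, reads were checked with FastQC and trimmed with Trimmomatic 0.38, transcripts were quantified with kallisto 0.44.0 on an Ensembl 79 index, and transcript values were summed to genes with tximport. The deposited table holds expected counts (kallisto estimated counts per gene), already rounded to whole numbers by the authors and not normalised. The authors' own test was DESeq2 at an adjusted p under 0.05 and over 2-fold. The table holds 41461 gene lines. The 5 lines that repeat 4 gene IDs were dropped, which leaves 41456 IDs, of which 41193 are in GENCODE M21 (GRCm38), the source of all coordinates. There are 72 IDs without a symbol, and 198 symbols stand on more than 1 ID.

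In counts of 1e+06, library totals ran from 3.12 to 46.97 in 21 libraries, and mutant ZT6 replicate 2 holds 7348 counts. A value of 0 allows up to 3 counts, which is 0.0639 to 0.961 CPM (counts scaled to a library total of 1e+06) in the 21 deep libraries and 408 in mutant ZT6 replicate 2. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates differed by far more than counting error: the lowest chi-square per degree of freedom of a pair of replicates was 27.81.

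All genes were tested in R 4.3.3 with edgeR 4.0.16: TMM factors, filterByExpr by group (min.count 10, min.total.count 15), and quasi-likelihood F tests (two-sided) in 1 fit of 6 groups over 22 libraries and 20763 genes, with Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05. Log2 fold changes are given ± a standard error (SE), taken as the absolute log2 fold change over the square root of its F statistic. It was not estimated by the fit itself and says little for genes at or near 0 counts in a group. The 10 comparisons are the genotypes within each state, their mean over the 3 states, SD within each genotype, ZT6 against ZT0 within each genotype, and the 2 interactions of genotype with SD and with time. Group values are means of TMM-scaled CPM ± SD. Sleep deprivation responses of the genotypes were also compared by correlation across genes. Hcrt and Pmch were tested between genotypes within each state by two-sided exact permutation tests on CPM, 6 tests in all.

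Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01), with camera at an estimated correlation, and with fry, on voom values of the same fit, with adjustment over the 30 lists of a comparison. The lists are the Prader-Willi imprinted locus, core clock, immediate early genes, heat shock and endoplasmic reticulum chaperones, cold-inducible RNA-binding proteins, feeding and arousal neuropeptides, their receptors, prohormone processing, transmitter identity, hypothalamic transcription factors, glucocorticoid-responsive genes, cholesterol synthesis, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation (OXPHOS), mitochondrially encoded genes, and markers of myelinating oligodendrocytes, oligodendrocyte precursors, astrocytes, microglia, endothelium and pericytes, choroid plexus, ependyma, tanycytes, pituitary, meninges and fibroblasts, blood, thalamus and habenula, cortex with hippocampus and amygdala, striatum, and sex-linked genes. Per library, a list is given as the sum of its members' CPM. Differences of a list within index sets are those of its members' mean log2 CPM from edgeR, with its default prior count.

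The comparisons, the lists and the rule for named genes were written before the data were examined. The rule names, in each comparison, the imprinted locus members, the called members of each list with the 4 largest changes as examples, the 10 largest called changes in each direction at a mean of at least 1 CPM, the 3 smallest p-values where fewer than 5 genes were called, and fixed genes (Hcrt, Pmch, Agrp, Npy, Pomc, Oxt and Avp between genotypes; Fos, Arc, Homer1, Hspa5, Cirbp, Per1, Per2 and Dbp for SD and time). Genes named beyond the rule are said to have been chosen after their values were seen.

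Alternative settings fixed in advance were the authors' 2-fold limit, RLE factors, DESeq2 1.42.0, no low-count filter (32403 genes), index numbers 43 to 46 as a covariate, 3 runs of index numbers as a covariate, leaving out the 4 libraries of index numbers 43 to 46, 1 surrogate variable (sva 3.50.0), a fit of only the groups of the comparison, and leaving out each library in turn. Index numbers are the ones in the sample titles, and the labels do not say whether they mark batches. Chosen after seeing the data were fits without 5 libraries (mutant ZT0 replicates 1 to 3 and mutant ZT6 replicate 3, which hold few transcripts of neurons and glia, and mutant ZT6 replicate 2), which leaves 17 libraries, and without 3 more with pituitary hormone transcripts (control ZT6 replicate 1, mutant SD replicates 1 and 4), which leaves 14. These were fitted with 3 index sets (index numbers 1 to 4, 5 to 18 and 43 to 46) as a covariate, by edgeR, and by limma-voom with quality weights; DESeq2 was also run on the 17. Leaving out each library in turn for the gene lists, with 22 and with 17 libraries, was added after seeing the data too. The 17-library fit with index sets is called the 17-library fit in the results. It cannot give any comparison that uses the mutant ZT0 group. Named genes that a gene near-identical to them or an overlapping gene on the other strand could share reads with (Ube3a with Snhg14, the Snord116 copies, Hspa1b with Hspa1a) have uncertain values.

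The procedure was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. All simulated libraries took their gene means and spread from the 17 libraries, at the real depths, with no difference between index sets. They include none like the 4 with few neural transcripts, so the rates below need not hold for the real 22-library fit. In the 22-library fit it recovered 4 to 88% of the 2-fold genes and 72 to 97% of the 4-fold genes, by comparison, and 0 to 6% of its calls were false. In the 17-library fit it recovered 14 to 54% and 58 to 85%. A simulated 1.5-fold rise of the 21 chaperones was called by camera, by camera with an estimated correlation (adjusted p = 5.13e-06) and by fry, with 0 of the 29 other lists called. The simulated genes varied independently of each other. This therefore does not show how the list tests behave where the members of a list move together. Reads were not analysed here, so alignment, splicing and the deletion's breakpoints were not examined. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.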

Results

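The data are gene counts from the hypothalamus of 22 mice, 11 control and 11 mutant. Control mice number 3 at ZT0, 4 at ZT6 and 4 after sleep deprivation (SD), and so do mutant mice. In counts of 1e+06, the control libraries total 29.72, 26.11 and 34.06 at ZT0, 46.97, 22.24, 16.07 and 14.61 at ZT6, and 36.42, 33.44, 24.72 and 21.74 after SD. The mutant libraries total 15.49, 32.16 and 3.12 at ZT0, 34.16, 0.007348, 17.77 and 28.38 at ZT6, and 33.83, 29.85, 23.83 and 18.23 after SD. The series asks how loss of paternal Snord116 and sleep deprivation change the hypothalamic transcriptome, with sleep and feeding in view.

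Transcripts of neurons, oligodendrocytes and astrocytes were few in 4 libraries, those labelled mutant ZT0 replicates 1, 2 and 3 and mutant ZT6 replicate 3. Myelin genes such as Mbp summed to 25.19 to 51.67 CPM there and to 3303 to 8811 CPM in the 17 other libraries of more than 7348 counts. The transmitter genes, which include the GABA enzyme Gad1 and the vesicular glutamate transporter Slc17a6, summed to 15.71 to 28.68 against 1077 to 1912 CPM. The astrocyte list summed to 108.9, 930.3, 574 and 557 CPM against 3457 to 4825, of which the gap junction gene Gja1 made up 77.01, 851.1, 475.9 and 462.4, and the neuropeptide list to 169, 944.2, 229.7 and 289.6 against 1496 to 5400, with the enkephalin precursor Penk at 902.6 in mutant ZT0 replicate 2 (both genes named after their values were seen). Over 93 neural genes the 4 libraries held 4.98, 8.07, 5.53 and 5.83% of the counts expected at their depth. Collagen genes stood high in the same 4: the meninges and fibroblast list summed to 11620 to 33130 CPM against 226.7 to 2768 in the 17. The homeobox (Hox) genes, which pattern the body axis behind the forebrain, summed to 191.3 to 414.9 CPM against 1.512 to 8.259. These values stand beside every comparison that uses the mutant ZT0 or mutant ZT6 group.

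Pituitary hormone genes were high in 3 other libraries. Their list, with growth hormone (Gh) and prolactin (Prl), summed to 20670 CPM in mutant SD replicate 1, 1141 in mutant SD replicate 4 and 659.4 in control ZT6 replicate 1, and to at most 35.71 in the other 14 of the 17. Libraries resembled those of their own index set: the median Spearman correlation was 0.975 with libraries of another group in the same set and 0.953 with libraries of the same group in another set. Sets 1, 2 and 3 hold 1, 2 and 1 control ZT6 libraries and 2, 1 and 1 control SD libraries. Of the mutant libraries in the 17, sets 2 and 3 hold 1 ZT6 library each and the sets hold 1, 2 and 1 SD libraries.

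**Figure D1:**
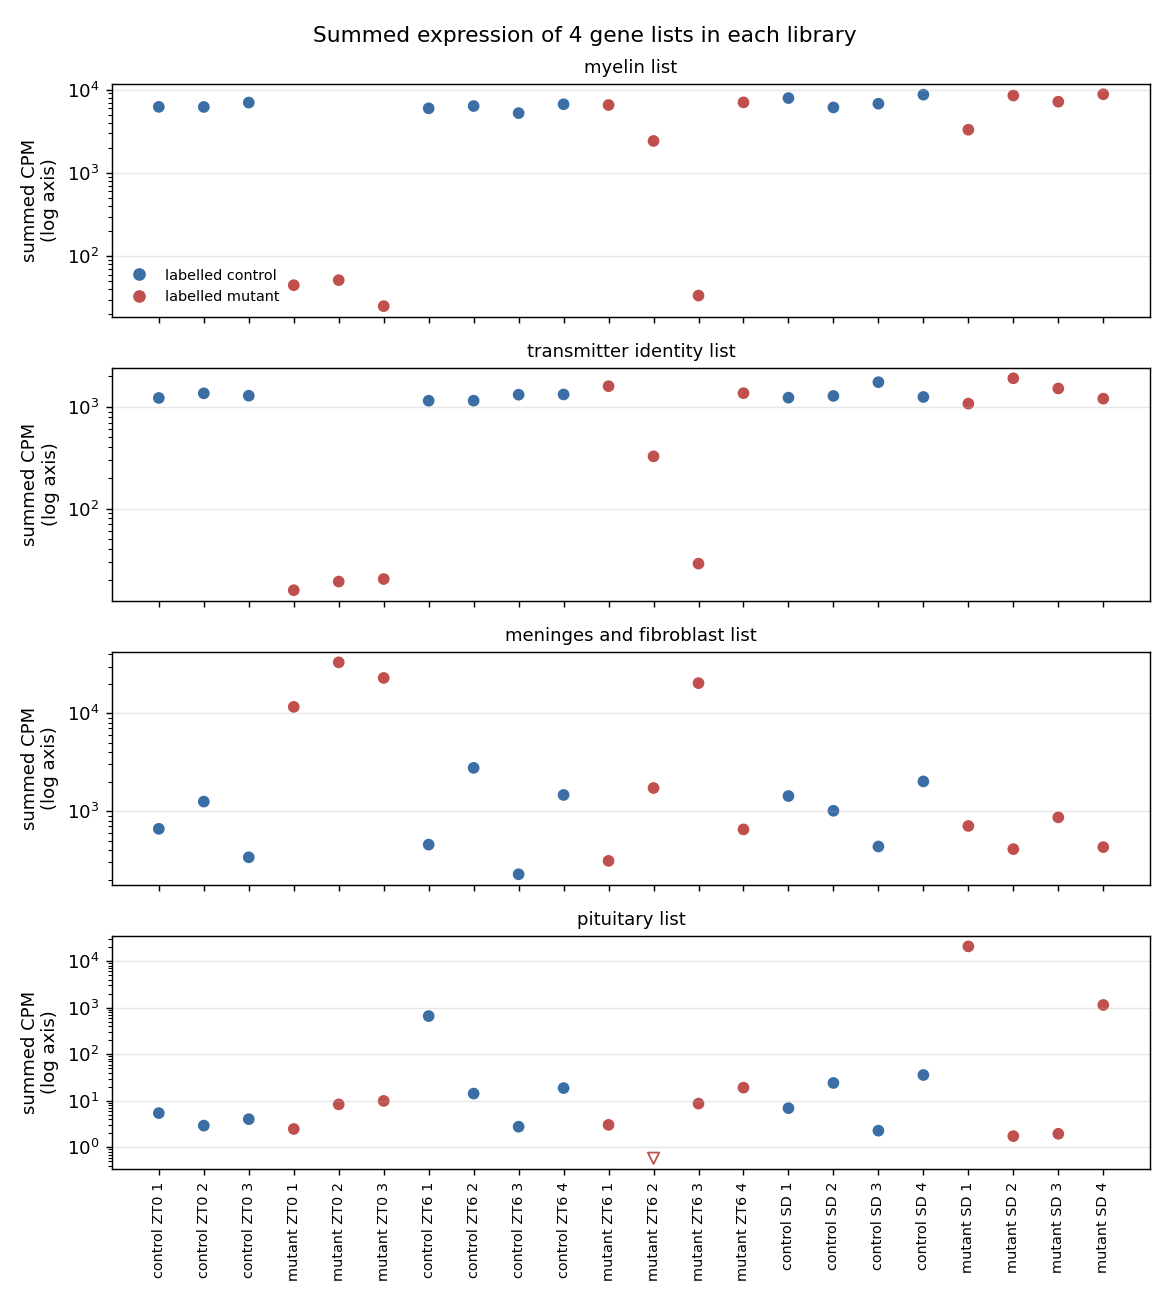
Summed CPM (log axis) of the myelin, transmitter, meninges and fibroblast, and pituitary lists in each of the 22 libraries; the open triangle is a value of 0. Myelin genes lie at 25.19 to 51.67 CPM in mutant ZT0 replicates 1 to 3 and mutant ZT6 replicate 3 and at 3303 to 8811 CPM in the 17 other libraries of full depth, and the pituitary list reaches 20670 CPM in mutant SD replicate 1.

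The first question is whether each library carries its labelled genotype at the deleted locus. Snord116, a cluster of C/D box small nucleolar RNAs within the introns of Snhg14 (chromosome 7, 59675988 to 59904848, GRCm38; 69 genes), gave 265, 232 and 3 counts in the control ZT0 libraries, 63, 5463, 67 and 0 in control ZT6, and 4, 6, 492 and 0 in control SD. All mutant libraries had 0 counts except mutant ZT6 replicate 1 with 4. In the 4 mutant libraries with few neural transcripts, 0 counts cannot be told apart from that lack, and mutant ZT6 replicate 2 holds 7348 counts. Of the 6 other mutant libraries 1 had counts. The 3, 4 and 6 counts of control ZT0 replicate 3 and control SD replicates 1 and 2 hardly differ from its 4. Counts were present in 9 of 11 control libraries. Those without were control ZT6 replicate 4 and control SD replicate 4, the controls of index set 3. Snhg14 did not separate the genotypes in that set either, at 233.1 and 187.1 CPM in these controls. It was at 213.4 and 204.1 CPM in mutant ZT6 replicate 4 and mutant SD replicate 4. Mutant libraries with 0 counts allow up to 0.961 CPM, and mutant ZT6 replicate 2 up to 408, while the control libraries with counts ranged from 0.0881 to 246 CPM. The neighbouring Snord115 cluster (126 genes, 59342226 to 59598982) gave 114, 104 and 182 counts in control ZT0, 134, 1349, 241 and 19 in control ZT6, and 88, 71, 199 and 13 in control SD. Mutant libraries gave 1, 0 and 0 at ZT0, 242, 0, 0 and 22 at ZT6, and 44, 218, 76 and 4 after SD. Libraries of polyadenylated RNA hold few small nucleolar RNAs, and counts of near-identical copies are uncertain.

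Snhg14, the host transcript of both clusters (minus strand, 59307924 to 59975759), averaged 569.2 ± 181 CPM (standard deviation, n = 3) in control and 58.66 ± 21.21 (n = 3) in mutant libraries at ZT0. It averaged 774.1 ± 759.6 against 140.9 ± 130.6 at ZT6 (n = 4 each) and 392 ± 145.3 against 283.2 ± 84.96 after SD (n = 4 each). Two-sided exact permutation tests gave p = 0.1, the smallest that 3 against 3 allows, p = 0.0571 and p = 0.229. Mutant ZT6 replicates 1 to 4 had 284.1, 0, 66.11 and 213.4 CPM, and replicates 1 and 4 alone average 248.7 ± 49.99 (n = 2, exact p = 0.467). Magel2 (62377010 to 62381640), which is expressed from the paternal copy, averaged 72.99 ± 9.443 CPM in control and 0.1025 ± 0.1776 in mutant libraries at ZT0 (n = 3 each), but 91.05 ± 25.33 and 69.87 ± 9.116 after SD (n = 4 each). Its neighbour Ndn (62346569 to 62350262) averaged 815.7 ± 64.33 and 139.7 ± 60.34 at ZT0, and 677.9 ± 75.23 and 863 ± 174.4 after SD. Ube3a had 0 counts in all control ZT0 libraries and shares sequence with the antisense Snhg14, so its values are uncertain.

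**Figure D2:**
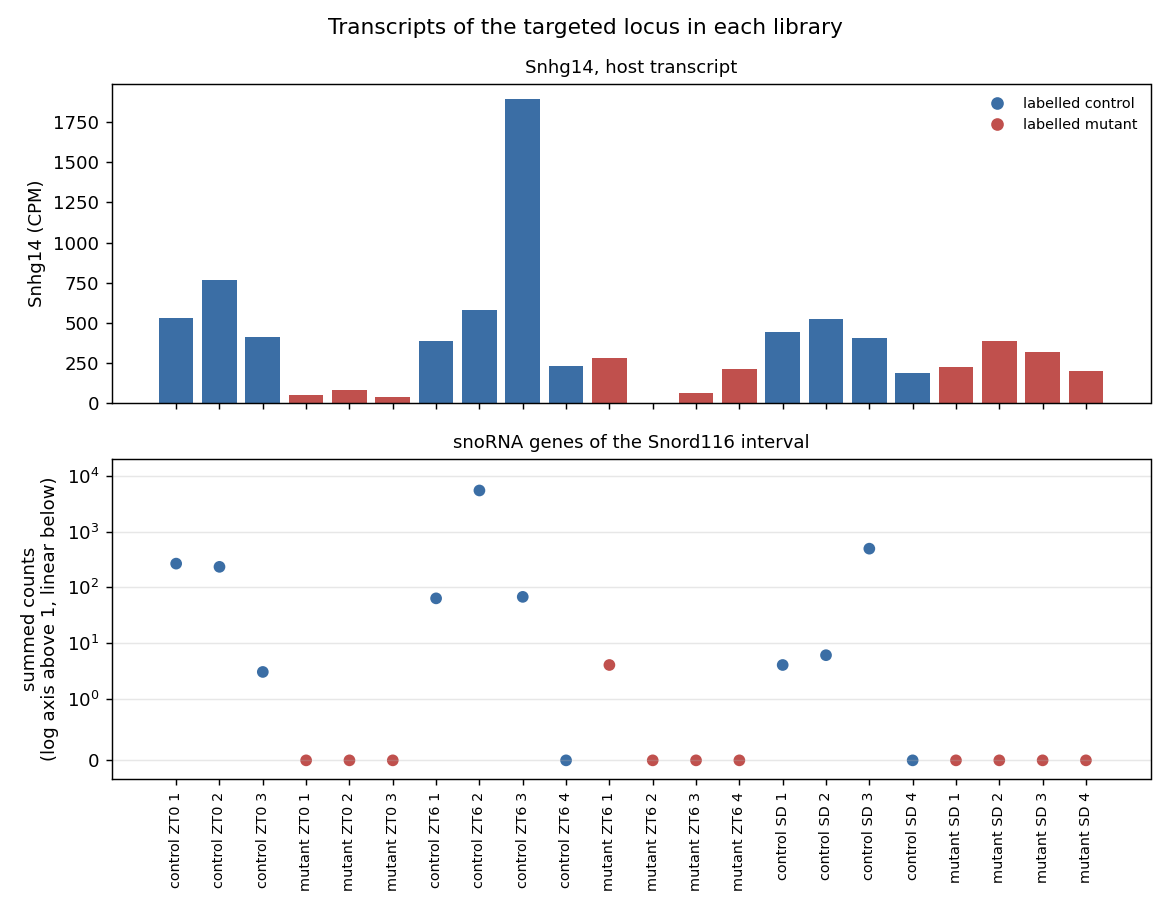
Snhg14 CPM (top) and summed Snord116 counts (bottom, log axis above 1 and linear below) in each of the 22 libraries. Snord116 has counts in 9 of 11 control libraries and in 1 mutant library (mutant ZT6 replicate 1, 4 counts). Only 6 mutant libraries lie outside the 4 with few neural transcripts and mutant ZT6 replicate 2, which holds 7348 counts.

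At ZT0, the comparison of mutant with control mice asks what Snord116 loss does at lights on. All 3 mutant ZT0 libraries are among the 4 with few neural transcripts, and no other library of that group exists. Neuronal genes fell: Gad1 by 9.88 ± 1.59 log2 (SE, n = 3 each), Slc17a6 by 9.92 ± 1.61, the thyrotropin-releasing hormone gene Trh by 10.67 ± 1.81 and melanin-concentrating hormone Pmch by 9.34 ± 1.60 (adjusted p = 0.000185). Glial genes fell too, with the astrocyte glutamate transporter Slc1a2 at −9.23 ± 1.25. Collagens rose, Col3a1 by 8.39 ± 2.27 and Col1a1 by 7.35 ± 2.05 (adjusted p = 0.00608), and so did the stress gene Cdkn1a, by 6.25 ± 1.23, and the cell cycle inhibitor Cdkn2a, by 13.12 ± 2.62. The fit called 4348 genes higher and 6063 lower in mutant libraries. Leaving out any of the 6 libraries gave 8693 to 9896 calls.

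Neurons and their peptides at ZT0 moved as follows. Of 32 neuropeptide genes 1 rose and 25 fell (2 and 26 adjusted over the list alone), median −7.49, or −5.71 with genes at 0 set to their bounds. Agrp and Npy, which drive feeding, changed by −4.95 ± 1.05 and −4.96 ± 0.99, oxytocin (Oxt) by −7.89 ± 1.62, vasopressin (Avp) by −8.32 ± 1.62 and orexin (Hcrt) by −7.57 ± 1.66 (adjusted p = 0.00112). Pomc was 0 in all mutant ZT0 libraries, at least 659-fold lower; floors here are 3 counts over the group. Of 22 receptors 20 fell (20 adjusted over the list alone; median −5.62; Drd2 at least 264-fold), of 12 prohormone processing genes 11 (11 over the list alone; median −8.47, −7.93 with bounds; Chga −9.68, Scg2 −9.33), and of 13 transmitter genes 12 (12; median −7.57, −5.18 with bounds; Slc32a1 −10.84 ± 1.73). Of 23 hypothalamic transcription factors 18 fell (18; median −4.84), with Nkx2-1 at least 657-fold and Lhx1 at least 212-fold lower. The calretinin gene Calb2 was at least 3480-fold and secretogranin Scg3 at least 1440-fold lower.

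Other cell types and regions at ZT0 moved in both directions. All 13 myelin genes fell (13 adjusted over the list alone, median −8.16), as did 9 of 10 astrocyte genes (9; median −6.06; Aqp4 −8.48). Oligodendrocyte precursor genes gave 3 up and 4 down of 7, microglia 1 and 4 of 10 (Cx3cr1 −5.09, Tmem119 +4.10), endothelium and pericytes 3 and 4 of 10 (3 and 5 over the list alone; Cldn5 −8.06), and tanycytes 1 and 4 of 7 (Adm +8.06). Of 9 choroid plexus genes 1 rose (Aqp1 +8.36) and 5 fell (median −5.98, −2.72 with bounds), and 6 of 7 ependymal genes fell. Of 5 blood genes 4 fell (5 over the list alone; median −9.52, −8.98 with bounds; Hba-a2 −11.91 ± 2.25). The thalamus and habenula list had 3 up and 3 down of 9 (median 0.38), cortex, hippocampus and amygdala 1 and 6 of 8 (median −6.74, −4.97 with bounds), striatum 0 and 5 of 7, and pituitary 0 and 1 of 9 (median −4.65, −1.18 with bounds). Of 9 meninges and fibroblast genes 6 rose and 3 fell (median 5.09). Of 5 sex-linked genes 1 rose and 1 fell (1 and 0 over the list alone), the rise being that of Xist, expressed from the inactive X chromosome, by 7.47 ± 1.57. It rests on mutant ZT0 replicate 2, without which Xist was at −0.15 (adjusted p = 0.848).

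At ZT0, of 21 immediate early genes 13 rose and 1 fell (14 and 1 adjusted over the list alone, median 3.22; Ptgs2 +8.27, Egr2 +6.43 ± 0.96, Ier2 +6.04), and 11 of 21 chaperones rose (11; median 1.36; Hspb1 +5.95 ± 1.30). Of 15 glucocorticoid-responsive genes 14 rose (14; median 3.50; Mt2 +5.19, Errfi1 +4.86). Ribosomal protein genes gave 70 up and 1 down of 81 (73 and 2; median 2.27; Rps2 +3.40 ± 0.65), cholesterol synthesis 3 up of 17, OXPHOS 6 up and 1 down of 72 (2 and 0), and mitochondrially encoded genes 6 down of 13 (5; median −1.38). Core clock genes gave 3 up and 9 down of 22, and of the cold-inducible genes Rbm3 rose by 2.30 and Cirbp fell, at −1.44. Within the imprinted locus 3 of 12 genes rose and 8 fell, Atp10a and Peg12 among the former, with Snhg14 at −3.28 ± 0.77 (adjusted p = 0.00186), Snrpn at −4.52 ± 0.87 and Magel2 at −8.71 ± 1.20. Camera called 12 lists at its preset correlation and 0 with an estimated correlation, where each adjusted p was 0.624 or more, for ribosomal proteins as for myelin, and fry called 14. The median over all genes was −0.22 log2 with TMM factors and 0 with RLE factors and DESeq2, which leaves these directions.

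At ZT6, the same comparison asks for the effect of genotype in mice that slept. Between 4 mutant and 4 control mice 0 genes passed the edgeR test, 2720 had an unadjusted p under 0.05, and DESeq2 called 670 higher and 17 lower. Eda2r, a receptor of the tumour necrosis factor family, at +6.93 ± 1.33, the non-coding 2810430I11Rik at +9.11 ± 1.75 and Ccn4, a matricellular protein gene, at +8.84 ± 1.70 came closest (adjusted p = 0.0571 for each). Peptide genes did not pass, with Agrp at −1.27 ± 0.76, Pomc at −4.25 ± 1.84 and Pmch at −0.26 ± 0.95. Snhg14 was at −2.27 ± 0.65 (adjusted p = 0.0838) and passed over the list alone, as did Atp10a at +1.92 ± 0.63. In the 17-library fit, which holds mutant ZT6 replicates 1 and 4 only, Snhg14 was at −1.20 ± 0.54 (adjusted p = 0.952).

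Gene groups at ZT6 split as mutant ZT6 replicate 3 did. All 13 myelin genes (median −0.46), 12 of 12 prohormone processing genes (−0.36), 21 of 22 receptors (−0.37), 12 of 13 transmitter genes (−0.57) and 8 of 10 astrocyte genes (−0.59) were lower, and neuropeptides (−0.38), hypothalamic transcription factors (−0.26), microglia (−0.54) and blood (−0.08) were called lower too. Of the others 68 of 81 ribosomal protein genes (0.39), 16 of 17 cholesterol synthesis genes (0.37), 13 of 15 glucocorticoid-responsive genes (1.52; 6 adjusted over the list alone, among them Cdkn1a +4.17 ± 0.98), 17 of 21 immediate early genes (1.22; 9 over the list alone, Ptgs2 +6.95 ± 1.49) and 17 of 21 chaperones (0.50; 4 over the list alone) were higher. Without that library the ribosomal median was −0.42, the glucocorticoid-responsive one −0.11, the immediate early one −0.15, the chaperone one 0.09, the myelin one 0.04 and that of neuropeptides 0.03. Camera called these 14 lists; with an estimated correlation all had an adjusted p of 0.488 or more, and fry called 0. In the 17-library fit, 10 of 10 endothelial and pericyte genes (−0.36) and 9 of 9 meninges and fibroblast genes (−1.21) were lower and no other list was called (adjusted p = 0.223 and 0.888 with an estimated correlation), the second without a call when control ZT6 replicate 2 (−0.95) or 4 (−1.27) was left out. Without mutant ZT6 replicate 1 the 22-library fit called 1356 genes, without mutant ZT6 replicate 4 1151, and without control ZT6 replicate 1 it called 1. With 17 libraries edgeR called 0 (905 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 16 up and 76 down. Of the mutant ZT6 libraries the 17 hold replicates 1 and 4 only. In simulated data the 17-library fit of this comparison recovered 26% of the 2-fold genes, so 0 calls do not show that the genotypes are alike.

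After sleep deprivation, the comparison of mutant with control mice asks whether sleep-deprived mice differ by genotype; none of these 8 libraries is among the 4 with few neural transcripts. The genes with the smallest p-values were the gonadotropin-releasing hormone receptor Gnrhr at +6.95 ± 1.75, Oacyl at +5.40 ± 1.48 and the enamel gene Tuft1 at +8.48 ± 2.19 (adjusted p = 1 for each). Peptide genes of the hypothalamus did not pass, with Hcrt at +0.65 ± 0.99, Pmch at −0.14 ± 0.94, Npy at −0.66 ± 0.70 and Oxt at 0.01 ± 0.96, nor did Snhg14 at −0.47 ± 0.61 or Magel2 at −0.38 ± 0.68. EdgeR called 0 genes (169 at an unadjusted p under 0.05) and DESeq2 6 up and 9 down. All 9 pituitary genes were higher (median 5.38, 6 adjusted over the list alone; Prl +10.36 ± 2.85), 80 of 81 ribosomal protein genes lower (−0.39), 69 of 72 OXPHOS genes lower (−0.41) and 10 of 15 glucocorticoid-responsive genes lower (−0.15), called by camera with adjusted p = 0.976 for each with an estimated correlation, and fry called 0. Without mutant SD replicate 1 the pituitary median was 1.02, with no call, and without control SD replicate 4 the ribosomal one was −0.18. The pituitary call was also lost without control SD replicate 1 (adjusted p = 0.147), 2 (0.0667) or 3 (0.385) or mutant SD replicate 4 (0.318). The glucocorticoid-responsive call was lost without mutant SD replicate 1 (−0.22) or 2 (0.02), and its median was −0.66 without mutant SD replicate 4.

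Within the 17-library fit of the same comparison, Prl rose by 11.05 ± 0.95 (adjusted p = 0.000297) and the luteinising hormone gene Lhb by 10.05 ± 0.72 (adjusted p = 0.00214), as did Gm14617, by 11.06 (adjusted p = 0.00695). These 3 calls go with mutant SD replicates 1 and 4, which hold 20670 and 1141 CPM of the pituitary list; without these and control ZT6 replicate 1 the 1 call was Igdcc4, named after its value was seen. Of 32 neuropeptides 25 were lower (median −0.37; adjusted p = 0.73 with an estimated correlation), Pmch at −0.64 ± 0.22 (adjusted p = 0.535) and Hcrt at −0.02 ± 0.51. OXPHOS genes were lower for 70 of 72 (−0.58) and ribosomal protein genes for 78 of 81 (−0.46), each with adjusted p = 0.73 with an estimated correlation; within sets 1, 2 and 3 the OXPHOS difference was −0.52, −0.27 and −0.72 log2 and the ribosomal one −0.16, −0.24 and −0.78. Without control SD replicate 4 the ribosomal median was −0.20. Camera also called the glucocorticoid-responsive (−0.12) and myelin (−0.15) lists (adjusted p = 0.73 for each with an estimated correlation), both without a call when control SD replicate 1 (−0.10 and −0.12) or mutant SD replicate 1 (−0.08 and 0.18) was left out. Pituitary genes (4.98) had a fry call (adjusted p = 0.000652; 0.0603 for camera with an estimated correlation), which was lost without mutant SD replicate 1 (2.33; fry 0.26). With an estimated correlation they passed without control SD replicate 1 (adjusted p = 0.047) or 4 (0.0146) or mutant SD replicate 4 (0.0275), and without the last the glucocorticoid-responsive list did too (−0.62, adjusted p = 0.0275). Limma-voom called 31 up and 0 down, but 0 genes without the 3 libraries with pituitary transcripts. DESeq2 called 142 up and 78 down.

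Averaged over the 3 states, the genotype comparison asks for a shared effect of Snord116 loss, with 3 mutant ZT0 libraries and 1 mutant ZT6 library with few neural transcripts among its 11 mutant libraries. Snhg14 fell by 2.00 ± 0.39 log2 (adjusted p = 0.000771, n = 11 each), Snrpn by 1.74 ± 0.41 and Magel2 by 3.32 ± 0.51. Peptide genes fell as well, Pmch by 3.25, Avp by 3.35, Agrp by 2.14 and Hcrt by 2.07 ± 0.70 (adjusted p = 0.0226). The Hcrt call was lost without control ZT0 replicate 2 (−1.67) or mutant ZT0 replicate 2 (−1.82). The largest rise was that of Cmah (+9.05), an enzyme of sialic acid metabolism, which did not pass without mutant SD replicate 1 (6.80), and the largest fitted fall that of Calb2 (−5.32). Calb2 had 0 counts in all mutant ZT0 libraries, so the size of its fall is not exact. EdgeR called 3585 genes up and 5220 down. All 13 myelin genes fell (median −3.05, −2.95 with bounds), 24 of 32 neuropeptides (−2.27, −2.12 with bounds; 25 adjusted over the list alone), 20 of 22 receptors (−2.14, −2.13 with bounds) and 11 of 12 prohormone processing genes (−2.83, −2.73 with bounds), while 14 of 21 immediate early genes (1.36), 11 of 21 chaperones (0.74), 12 of 15 glucocorticoid-responsive genes (1.59; 13 over the list alone) and 40 of 81 ribosomal protein genes (0.76; 42 over the list alone) rose. Without mutant ZT6 replicate 3 the glucocorticoid-responsive and ribosomal medians were 1.03 and 0.48. Camera called 14 lists (adjusted p of 0.545 or more with an estimated correlation) and fry 15. With 3 runs of index numbers as a covariate 2451 genes were called and Snhg14, at −1.46, was not (adjusted p = 0.0536), and the ZT6 and SD comparisons taken alone gave 0.

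Orexin and melanin-concentrating hormone mark the lateral hypothalamic neurons that the series names. Hcrt (ENSMUSG00000045471) averaged 0.283 ± 0.417 CPM in mutant and 60.9 ± 59.5 in control mice at ZT0 (n = 3 each), 63.6 ± 79.6 and 47.9 ± 16.6 at ZT6 (n = 4 each), and 105.2 ± 73.9 and 66.9 ± 49.8 after SD (n = 4 each). Pmch (ENSMUSG00000035383) averaged 0.842 ± 0.676 and 584.4 ± 169.4 at ZT0, 513.1 ± 537.2 and 637.4 ± 210.7 at ZT6, and 690.1 ± 373.4 and 763.1 ± 331.1 after SD. Two-sided exact permutation tests gave p = 0.1 for each gene at ZT0, the smallest possible with 3 against 3 (adjusted over 6 tests, 0.3). These exact tests gave p = 0.743 for Hcrt and 0.686 for Pmch at ZT6, and p = 0.4 and 0.743 after SD (4 against 4 allows 0.0286; adjusted p = 0.743 for all 4). All mutant ZT0 libraries and mutant ZT6 replicate 3 have few neural transcripts, and 0 counts in mutant ZT6 replicate 2 allow up to 408 CPM. The tests at ZT0 and ZT6 therefore cannot show whether genotype changes these genes. With mutant ZT6 replicates 1 and 4 alone, Hcrt averaged 127.2 ± 53.5 CPM (n = 2, exact p = 0.0667, the smallest possible) and Pmch 932.8 ± 379.5 (exact p = 0.4).

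**Figure D3:**
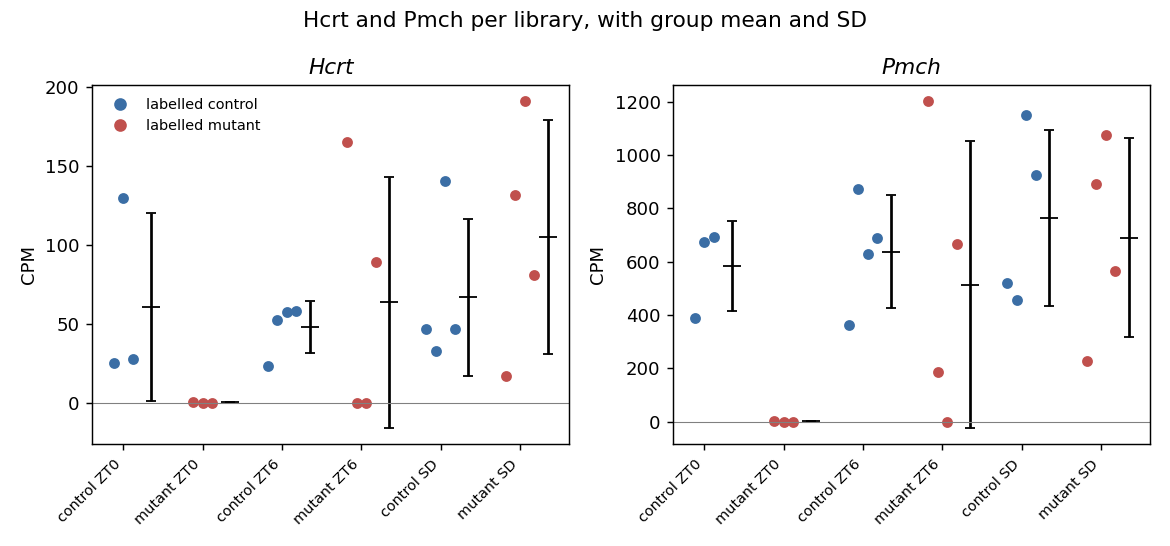
Hcrt and Pmch CPM in each library, with group means and standard deviations, by genotype and state. Hcrt averages 105.2 CPM in mutant and 66.9 CPM in control mice after sleep deprivation. Both genes lie near 0 in mutant ZT0 libraries and in mutant ZT6 replicate 3, all of which have few neural transcripts.

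In control mice, the comparison of SD with ZT6 asks for the response to 6 h without sleep. Glucocorticoid-responsive genes were higher for 15 of 15 members (median 0.91) and chaperones for 21 of 21 (median 0.57). Sgk1, a kinase gene that glucocorticoids induce, averaged 98.77 ± 23.56 CPM after SD and 20.45 ± 4.226 at ZT6 (n = 4 each; +2.27 ± 0.68 log2), and Tsc22d3, an anti-inflammatory glucocorticoid target, 166.6 ± 29.73 and 79.86 ± 25.85; both passed adjusted over the list alone. Camera called both lists (1.36e-15 and 1.24e-14; adjusted p = 0.0954 for each with an estimated correlation), and fry called 0. Without control SD replicate 4 the medians were 0.61 and 0.36, both called. Camera called OXPHOS as well, with 42 of 72 genes higher (median 0.03, 0.00886; adjusted p = 0.949 with an estimated correlation), but not without control ZT6 replicate 1 (−0.08), 3 (−0.16) or 4 (−0.03) or control SD replicate 4 (−0.15), and without control ZT6 replicate 2 its median was 0.44. Over all genes edgeR called 0 (700 at an unadjusted p under 0.05; 1 without control ZT6 replicate 1) and DESeq2 10 up and 9 down. The smallest p-values were those of Gm26686 (−1.66), Gm14853 (−4.82) and Gm17571 (−5.48), with an adjusted p of 1.

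Chaperones and cold-inducible genes stood out more in the 17-library fit of control mice. Of 21 chaperones 14 passed adjusted over the list alone, among them Hsph1 (+0.75 ± 0.23), Chordc1 (+1.01 ± 0.18), Hspa5 (+0.56 ± 0.17), the main chaperone of the endoplasmic reticulum, and Hspa1b (+1.18 ± 0.25, uncertain beside Hspa1a). The rule names Hspa5, Sgk1, Cirbp, Fos, Arc, Homer1, Per1, Per2 and Dbp. The other genes of this paragraph were named after their values were seen. Of 15 glucocorticoid-responsive genes 9 passed (Sgk1 +2.26 ± 0.35, adjusted p = 0.108 over all genes; Plin4 +2.05 ± 0.60; Klf9 +0.49 ± 0.15), and of 3 cold-inducible genes 2, Cirbp at −0.61 ± 0.13 and Rbm3 at −0.69 ± 0.14. Fry called these 3 lists (adjusted p = 0.012, 0.0149 and 0.0149), and camera did so at its preset but not with an estimated correlation (adjusted p = 0.0613, 0.0613 and 0.0871). The fry calls did not hold without control ZT6 replicate 4 (adjusted p = 0.052, 0.0637 and 0.0637), those of the last 2 lists without control ZT6 replicate 1 (0.0503 for each) and the cold-inducible one without control SD replicate 4 (0.0958). Without control SD replicate 2 the chaperones passed with an estimated correlation (adjusted p = 0.04). The preset camera calls held without any of the 8 libraries, at medians of 0.44 to 0.62, 0.78 to 1.00 and −0.70 to −0.53. Within index sets 1, 2 and 3 the mean chaperone difference was 0.38, 0.54 and 0.67 log2, that of glucocorticoid-responsive genes 0.96, 0.78 and 1.19, and that of cold-inducible genes −0.40, −0.22 and −0.65. Fos (−0.22), Arc (−0.21), Homer1 (0.07), Per1 (−0.12), Per2 (−0.17) and Dbp (−0.33) did not pass.

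The 17-library fit of control mice also called 7 other lists by camera. Higher were neuropeptides (median 0.13; adjusted p = 0.367 with an estimated correlation), receptors (0.14; 0.0871), prohormone processing (0.12; 0.297; Vgf +0.82 ± 0.19 passed over the list alone), transmitter genes (0.23; 0.297), OXPHOS (0.08; 0.818) and myelin (0.28; 0.527). Each of these 6 calls was lost without at least 1 library: without control ZT6 replicate 3 neuropeptides were at 0.05, prohormone processing at 0.06, transmitter genes at 0.16, OXPHOS at −0.06 and myelin at 0.22, and without control SD replicate 2 receptors were at 0.11. Pituitary genes were lower for 9 of 9, with control ZT6 replicate 1 the library that holds them (−3.41; adjusted p = 0.101 with an estimated correlation; fry 0.0253, lost without that library, 0.134, control ZT6 replicate 4, 0.0637, or control SD replicate 1, 0.068). EdgeR called 0 genes (1952 at an unadjusted p under 0.05), limma-voom 38 up and 35 down, with Sgk1 at +2.21 and Tsc22d3 at +1.16 among those up, and DESeq2 115 up and 114 down. Without the 3 libraries with pituitary transcripts edgeR called 2 up and 2 down, which were Sgk1 (+2.31) and Pck2 (+10.81) and Igdcc4 (−4.16) and Amy2a5 (−9.20), named after their values were seen.

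**Figure D4:**
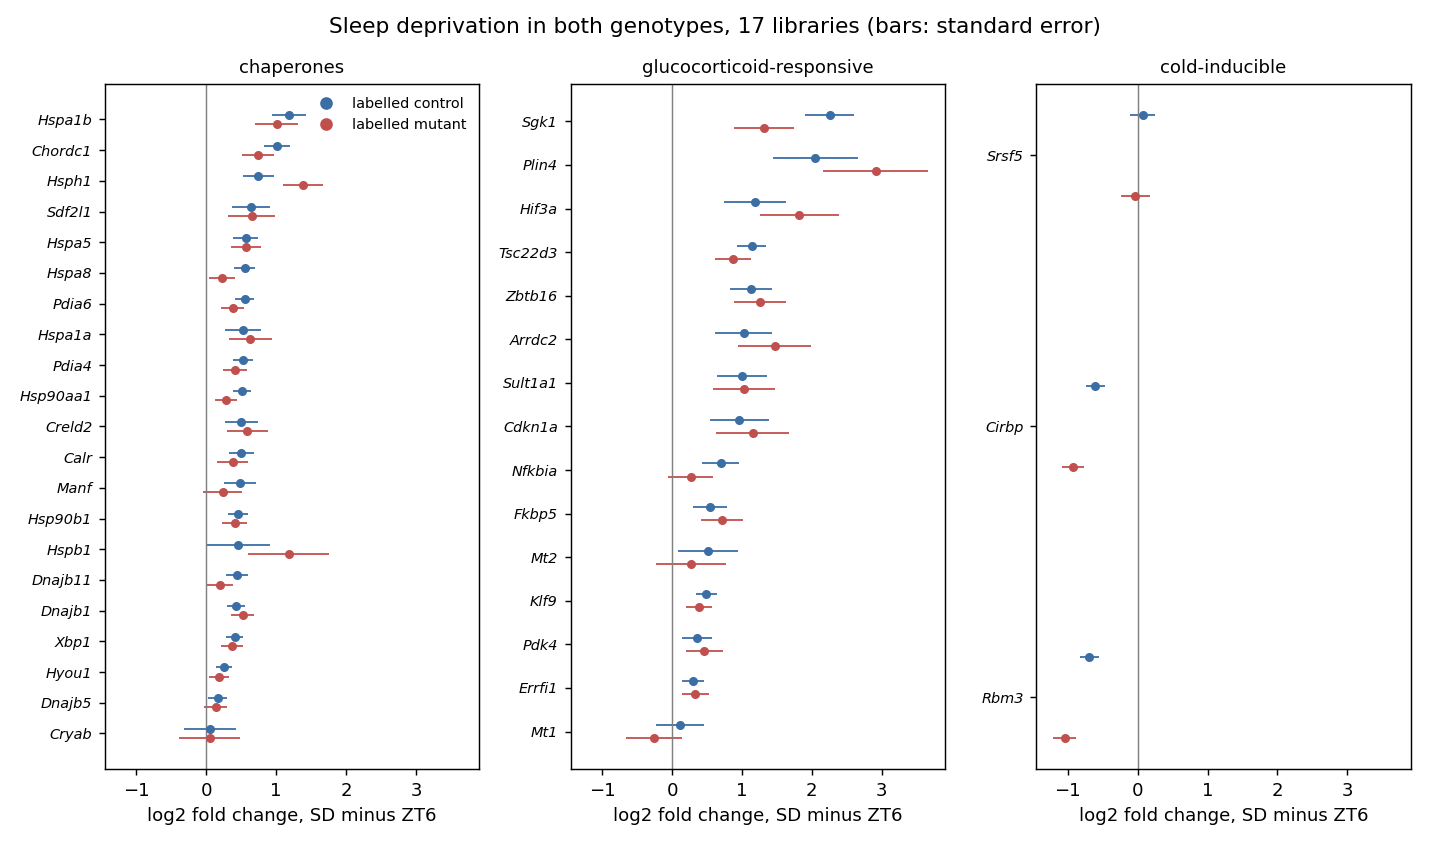
Log2 fold change (SE) of SD against ZT6 for each gene of the chaperone, glucocorticoid-responsive and cold-inducible lists in control and mutant mice, 17-library fit. Sgk1 is at +2.26 ± 0.35 in control and +1.32 ± 0.43 in mutant mice, and Rbm3 at −0.69 ± 0.14 and −1.05 ± 0.16.

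In mutant mice, SD against ZT6 asks the same question, with mutant ZT6 replicate 3 low in neural transcripts and replicate 2 holding 7348 counts. Genes that replicate 3 expresses highest fell: the prostaglandin synthase gene Ptgs2 by 6.30 ± 1.43 log2 (n = 4 each), adrenomedullin (Adm) by 5.74 ± 1.24, Hoxc6 by 11.50 ± 2.59, the chemokine Ccl2 by 10.83 ± 2.54, the imprinted non-coding H19 by 9.43 ± 2.23 and Cdkn2a by 9.19 ± 1.92 (adjusted p = 0.0499 for each). EdgeR called 1 gene up and 172 down, and DESeq2 17 and 682. With index numbers 43 to 46 as a covariate 0 genes were called (adjusted p = 0.0791 for each gene above) and with 1 surrogate variable 0. With 3 runs of index numbers 2 others were, and Ptgs2 was at +0.76, Adm at +0.25, Hoxc6 at +2.38, Ccl2 at +0.61, H19 at +0.66 and Cdkn2a at −0.13. Without mutant ZT6 replicate 2 or 3, or any of the 4 mutant SD libraries, 0 were called. Without replicate 3 Ptgs2 was at −0.39, Adm at 0.46, Ccl2 at −1.20, H19 at −0.62, Cdkn2a at −1.07 and Hoxc6 at 0. Without mutant ZT6 replicate 1 or 4 there were 1231 and 1111 calls. Immediate early genes gave 1 fall of 21 (10 adjusted over the list alone, Fos −1.62 ± 0.47 among them, which did not pass over all genes), and 77 of 81 ribosomal protein genes (median −0.87) and 17 of 17 cholesterol synthesis genes (−0.50) were lower, with 22 of 22 receptors (0.65), 12 of 12 prohormone processing genes (0.72), 13 of 13 transmitter genes (0.67) and 12 of 13 myelin genes (0.71) higher. Without replicate 3 these medians were −0.05, −0.12, 0.13, 0.27, 0.14 and 0.15. Camera called 15 lists (adjusted p of 0.494 or more with an estimated correlation), fry 0.

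In the 17-library fit of mutant mice (4 SD libraries against ZT6 replicates 1 and 4), 3 of 3 cold-inducible genes were lower (median −0.93). Rbm3 (named after its value was seen, as are the genes below) was at −1.05 ± 0.16 and Cirbp at −0.93 ± 0.16. Both passed over the list alone but not over all genes (adjusted p = 0.2 and 0.329). Chaperones were higher for 21 of 21 (0.41; 4 adjusted over the list alone, with Hsph1 at +1.38 ± 0.29). These 2 lists were called by camera, with an estimated correlation (adjusted p = 0.0196 and 0.0444) and by fry (adjusted p = 0.00879 and 0.0481). The last 2 tests lost calls when single libraries were left out, which also leaves fewer libraries to test. With an estimated correlation the cold-inducible call was lost without mutant ZT6 replicate 1 (adjusted p = 0.102) or 4 (0.133) or mutant SD replicate 1 (0.0578), and the chaperone call without mutant ZT6 replicate 1 (0.0975) or 4 (0.351) or mutant SD replicate 1 (0.0578), 2 (0.0558) or 3 (0.0738). By fry the chaperone call was lost without any 1 of the 6 libraries and the cold-inducible one without mutant ZT6 replicate 1 (0.132) or 4 (0.203) or mutant SD replicate 4 (0.0854). The preset camera calls held without each library, at medians of −0.99 to −0.84 and 0.30 to 0.56. Glucocorticoid-responsive genes were higher for 14 of 15 (0.87; 6 over the list alone, Sgk1 +1.32 ± 0.43 and Zbtb16 +1.26 ± 0.37; adjusted p = 0.0702 with an estimated correlation), at 0.55 without mutant ZT6 replicate 4. Mitochondrially encoded genes were lower for 13 of 13 (−0.41; adjusted p = 0.207 with an estimated correlation), cholesterol synthesis for 16 of 17 (−0.28; 0.135), and hypothalamic transcription factors for 16 of 23 (−0.19; 0.0836; fry 0.0481). The last 2 were at −0.18 and −0.04 without mutant ZT6 replicate 1 and not called. Ribosomal (−0.19), OXPHOS (−0.19), ependymal (−0.39), fibroblast (0.78) and pituitary (4.02) lists were called by camera only, with estimated-correlation adjusted p = 0.894, 0.851, 0.661, 0.661 and 0.0836. The first 4 were not called without mutant ZT6 replicate 1 (−0.07, −0.12, −0.29 and 0.70), nor pituitary genes without replicate 4 (2.54). Within index sets 2 and 3, the chaperone difference was 0.39 and 0.54 log2, the glucocorticoid-responsive one 0.49 and 1.63, and the cold-inducible one −0.68 and −0.71; set 1 holds no mutant ZT6 library. EdgeR called 0 genes (662 at an unadjusted p under 0.05), limma-voom 2 up and 1 down and DESeq2 76 up and 21 down.

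The interaction of genotype with SD asks whether mutant and control mice respond differently to sleep loss. Chaperones (median −0.05), glucocorticoid-responsive genes (0.04) and cold-inducible genes (−0.32) were not called in the 17-library fit by camera (adjusted p = 0.461, 0.482 and 0.124). Across genes, which are not independent replicates, the SD changes of the genotypes correlated with r = 0.0259 in that fit and 0.0374 in the 22-library fit (Spearman 0.0833 and 0.106), and 51.7 and 54.2% of genes had the same sign. Over the 39 chaperone, glucocorticoid-responsive and cold-inducible genes alone, r was 0.874 in the 17-library fit, with 37 of the same sign. With 22 libraries it was 0.115, with 19 of the 39 of the same sign. These lists were not singled out in advance, and each had moved the same way in both genotypes in the 17-library fit. The r over them is therefore no separate evidence of a shared response. EdgeR called 0 genes with 22 libraries (1397 at an unadjusted p under 0.05; 1 without control ZT6 replicate 1), with Rtl3 (−11.69), 2810430I11Rik (−10.51) and Aspn (−8.17) closest (adjusted p = 0.458), and DESeq2 called 10 up and 108 down. With 17 libraries edgeR called 0 (846 at an unadjusted p under 0.05), limma-voom 3 up and DESeq2 74 up and 15 down. Prl (+13.56), Lhb (+12.82) and Gm14617 (+12.01) were closest (0.0568 for Prl). Camera called 14 lists with 22 libraries, among them ribosomal proteins (77 of 81 lower, −0.76), glucocorticoid-responsive genes (14 of 15 lower, −1.43) and immediate early genes (18 of 21 lower, −1.44), which were at 0.00, 0.02 and −0.03 without mutant ZT6 replicate 3, with adjusted p of 0.505 or more with an estimated correlation, and 9 with 17, among them OXPHOS (66 of 72 lower, −0.28; adjusted p = 0.668 with an estimated correlation), at −0.64 without control ZT6 replicate 2, −0.14 without replicate 3 and −0.13 without replicate 4. DESeq2 shifted the median of all genes to −0.28 log2, RLE factors to 0.17 and TMM to 0.07.

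In control mice, ZT6 against ZT0 asks for the change over the first 6 h of light. Nuclear OXPHOS genes, which build the respiratory chain, were higher for 70 of 72 members (median 0.56), ribosomal protein genes for 75 of 81 (0.58), and mitochondrially encoded genes lower for 12 of 13 (−0.50), each called by camera (adjusted p = 0.924, 0.94 and 0.924 with an estimated correlation). The first 2 shifts rest on control ZT6 replicate 2, without which the medians were 0.09 and 0.13 with no call (adjusted p = 0.394 and 0.864). Pituitary genes were higher for 9 of 9 (3.74; adjusted p = 0.94), with control ZT6 replicate 1 the library that holds them (2.27 without it, not called). The clock output gene Dbp averaged 52.09 ± 23.69 CPM at ZT6 (n = 4) and 21.97 ± 3.96 at ZT0 (n = 3); it was at +1.25 ± 0.66 log2 and did not pass. With 17 libraries Dbp (+0.95 ± 0.22), Nr1d1 (+0.65 ± 0.16, named after its value was seen) and Cirbp (+0.61 ± 0.15) passed adjusted over their lists alone. Camera called 8 lists in that fit, with OXPHOS at 0.66, ribosomal proteins at 0.60 and mitochondrially encoded genes at −0.58 (adjusted p of 0.547 or more with an estimated correlation, and 0 calls by fry). All ZT0 libraries are in set 2, as are control ZT6 replicates 2 and 3, and without replicate 2 the 3 medians were 0.09, −0.05 (not called) and −0.32. EdgeR called 0 genes with 22 libraries (244 at an unadjusted p under 0.05; 1 without control ZT0 replicate 3, control ZT6 replicate 1 or control ZT6 replicate 2), with Eif4a-ps4 (+12.05), Rassf9 (+7.24) and Gm22030 (−3.46) closest, and DESeq2 30 up and 6 down. With 17 libraries edgeR called 0 (1631), with Mmp3 (−7.39), Gm28557 (−2.38) and Banp (−0.82) closest (adjusted p = 0.53), limma-voom 0 and DESeq2 73 up and 54 down.

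In mutant mice, ZT6 against ZT0 sets 4 libraries, of which replicate 3 has few neural transcripts, against 3 that all have few. Neural genes rose, with Trh at +11.12 ± 1.82 log2, Gad1 at +9.49 ± 1.56, Magel2 at +7.82 ± 1.17 and Snrpn at +4.31 ± 0.85. The clock gene Dbp rose by 3.85 ± 0.80 (adjusted p = 0.00127) and Cirbp by 1.87 ± 0.50, with no call without mutant ZT6 replicate 4 (1.30). Fos fell by 1.78 ± 0.51 (adjusted p = 0.0134), with no call without mutant ZT6 replicate 1 (adjusted p = 0.0611) or 4 (0.0659). The inflammatory genes Nos2 and Saa3 fell by 14.71 and 11.28, and both rest on mutant ZT0 replicate 2, without which they were at −4.44 and −1.50 and did not pass. EdgeR called 4372 genes up and 574 down. All 13 myelin genes (median 7.48), 24 of 32 neuropeptides (7.01, 5.64 with bounds), 18 of 23 hypothalamic transcription factors (3.98) and 9 of 10 astrocyte genes (5.61) rose, and 6 of 15 glucocorticoid-responsive genes (−1.62), 7 of 21 immediate early genes (−1.30; 1 rose), 4 of 21 chaperones (−0.88; 2 adjusted over the list alone) and 14 of 81 ribosomal protein genes (−1.29; 1 rose; 0 over the list alone) fell. These last 4 medians were −3.29, −3.14, −1.32 and −2.12 without mutant ZT6 replicate 3. Camera called 14 lists (adjusted p = 0.618 or more with an estimated correlation), fry 4. A fit of these groups alone called 0, and leaving out mutant ZT6 replicate 3 gave 10207 calls.

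The interaction of genotype with time asks whether the change over the light phase differs by genotype, and it carries the same libraries. Neural genes rose more in mutant mice: Pmch by 9.08 ± 1.74 log2 (adjusted p = 0.00176), Hcrt by 8.27 ± 1.90, Gad1 by 9.57 ± 1.73 and Magel2 by 7.84 ± 1.34, while Xist fell by 8.15, and without mutant ZT0 replicate 2 it was at −0.54 and not called. Ndn, at +2.20 ± 0.76, did not pass (adjusted p = 0.0557). EdgeR called 3061 genes up and 152 down. All 13 myelin genes (median 7.63), 21 of 32 neuropeptides (6.92, 5.33 with bounds; 23 adjusted over the list alone), 14 of 22 receptors (5.35; 20 over the list alone) and 11 of 13 transmitter genes (7.48, 4.61 with bounds; 12 over the list alone) rose, and 8 of 81 ribosomal protein genes (−1.78; 0 over the list alone), 5 of 21 immediate early genes (−1.50; 6) and 2 of 15 glucocorticoid-responsive genes (−1.83; 4) fell, at −2.72, −3.36 and −3.64 without mutant ZT6 replicate 3. Camera called 15 lists (adjusted p of 0.543 or more with an estimated correlation), fry 1. Without mutant ZT6 replicate 3 there were 8530 calls, without the 4 libraries of index numbers 43 to 46 1797, and in a fit of these groups alone 1582.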

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

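The tests of the 4 libraries with few neural transcripts, of the pituitary transcripts and of the index sets, and the splits of the limma-voom counts, were chosen after the result was seen; the other splits were chosen before.

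Single libraries stood apart in 12 of 92 groups of 4 tested over 23 measures: 1 library lay further from the nearest of the other 3, relative to the range of the group, than Dixon's 95% limit allows. For independent, normally distributed values chance would pick about 1 in 20 groups. CPM and counts need not be such values, measures such as Pomc and the pituitary list are related, and any count beside 0 in the other 3 is flagged. The 12 of 92 therefore do not measure an excess over chance. In mutant ZT6 replicate 2, which holds 7348 counts, 2149 genes were detected (21610 to 24190 in the other 3) and Homer1 was at 0 CPM (21.91 to 25.7). The pituitary list stood at 659.4 CPM in control ZT6 replicate 1 (2.772 to 18.7 in the others) and at 20670 in mutant SD replicate 1 (1.742 to 1141). Pomc, which the pituitary expresses as well, was at 1121 CPM in control ZT6 replicate 1 (23.74 to 85.86) and at 4065 in mutant SD replicate 1 (19.23 to 104.6). Hcrt was at 140.9 CPM in control SD replicate 3 (33.15 to 47.03), Homer1 at 40.31 in control ZT6 replicate 3 (17.16 to 20.28) and Dbp at 50.24 in mutant SD replicate 1 (26.4 to 30.45). Snord116 counts were 5463 in control ZT6 replicate 2 (0 to 67), 492 in control SD replicate 3 (0 to 6) and 4 in mutant ZT6 replicate 1 (0 in the other 3). The interaction test of genotype with time called 3213 genes. All mutant ZT0 libraries and mutant ZT6 replicate 3 have few neural transcripts, and 4 of 40 splits, the real one included, called as many. Whether the effect of genotype itself changed between ZT0 and ZT6 stays open.

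RNA from a tissue or cell culture other than hypothalamus may account for mutant ZT0 replicates 1, 2 and 3 and mutant ZT6 replicate 3. Too few counts are argued against, since the 4 hold at most 8.07% of the neural counts expected at their depth, and so is Snord116 loss, since each of the 6 other mutant libraries holds 93% or more. Of the 9 genes of the meninges and fibroblast list 5 (all of which the control libraries also express, at 2.615 CPM or more) are higher in all 4 than in every control library, with Col1a1 at 5568 to 7998 CPM (2.615 to 97.51 in controls) and Col1a2 at 4666 to 8385 (12.76 to 113.2), while Ptgds of the meninges stands at 1.544 to 24.17 (170 to 2575). Among genes picked for being high in these 4, Lox is at 4089 CPM or more (at most 16.07 in the 17) and H19 at 1550 or more (5.836), and 37, 37, 36 and 38 of 39 Hox genes are detected, against 9 to 18 in the 17. Which tissue it was, and whether sample or label was exchanged, stays open, as does the effect of genotype at ZT0.

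Pituitary tissue in the dissected sample is a candidate source of the hormone transcripts in mutant SD replicates 1 and 4 and control ZT6 replicate 1. Genotype is argued against, since the 4 other mutant libraries of the 17 sum to at most 19.1 CPM of the list. Of the 9 genes 5 are higher in each of the 3 than in all 14 others, with Gh at 17320, 964.1 and 531.8 CPM (at most 14.84 elsewhere) and Prl at 2155, 138.6 and 49.64 (3.174). The 3 libraries were picked for Gh and Prl, so the tally holds these genes by selection. Its other members are Cga, Fshb and Lhb. A difference in hormone expression itself between these mice was not tested.

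Differences between library or sequencing batches may underlie the resemblance of libraries by index set. Over the 17 libraries the 3 sets accounted for 0.933 of the first principal component, which holds 23.3% of the variance (permutation p = 1e-04, the smallest that 10000 permutations can give), and for 0.755 of the second. The limits of the sets were chosen after seeing these data and differ from the 3 runs fixed in advance. The permutation p does not allow for that choice. Genotype, time and sleep deprivation as its source are argued against, since the 5 groups accounted for 0.216 of the first and 0.121 of the second. The labels give index numbers only, so what the sets were stays open, and sets 1 and 3 hold no ZT0 library.

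Other splits of the same libraries were fitted in the same way, and the tallies below count the real split. Chance could not be excluded for genotype over the 3 states, genotype by time, time in mutant mice, SD in mutant mice and the 2 limma-voom counts. At ZT0 the 10 splits are too few for a share under 0.05; the real one called 10411 genes and the highest other 0, so 1 of 10, the real split itself, reached that count. For genotype over the 3 states 4 of 40 splits called as many as the real 8805 (highest other 9629), and for genotype by time 4 of 40 as many as 3213 (9247). For time in mutant mice 8 of 35 called as many as 4946, and the highest, 10675, set mutant ZT0 replicates 1 to 3 and mutant ZT6 replicate 3 against the others. For SD in mutant mice 12 of 35 called as many as 173, and the highest, 1009, set mutant ZT6 replicates 2 and 3 on one side. With 0 real calls every split reaches the real count by construction, so these counts say nothing about chance: 35 of 35 for genotype after SD (highest other 0), SD in control mice (0), time in control mice (1) and genotype at ZT6 (965), and 40 of 40 for genotype by SD (780). Limma-voom with 17 libraries gave 8 of 35 splits as high as 31 for genotype after SD (1432) and 6 of 35 as high as 73 for SD in control mice (1409). Splits that call several times the real count point to a structure of the samples other than the groups; the 965 calls at ZT6 come from a split with both set 3 libraries on one side, and with 3 runs of index numbers as a covariate the real split called 2.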

How the results depend on the processing

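Fits without 5 or 8 libraries and with 3 index sets, and lists with 1 library left out, were chosen after seeing the data; the other settings were fixed before the data were examined. For the changes below that a smaller set of libraries or genes does not account for by itself, the cause was not tested. Depth limits mutant ZT6 replicate 2 (7348 counts) most, and comparisons with mutant ZT0 could not be fitted without the 5 libraries, since no library of that group is left; for genotype over the 3 states, a fit of only the groups is the fit of all 22 libraries.

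Counts of calls at ZT0 stayed within 1.5 times of 10411 under all settings run. Under the 2-fold limit, RLE factors, 1 surrogate variable and index numbers 43 to 46 as a covariate so did all other counts, except that the last 2 gave 0 for SD in mutant mice. With DESeq2 there were 687 calls for genotype at ZT6, 15 for genotype after SD, 19 for SD in control mice, 699 for SD in mutant mice, 118 for genotype by SD and 36 for time in control mice. Without a low-count filter, genotype at ZT6 gave 328 and SD in mutant mice 349. With 3 runs of index numbers as a covariate, genotype over the 3 states gave 2451, and genotype at ZT6, SD in mutant mice, genotype by SD and time in control mice gave 2 each. Without index numbers 43 to 46, genotype at ZT6 gave 501, SD in mutant mice 382, time in mutant mice 3075 and genotype by time 1797. With only the groups compared, SD in mutant mice and time in mutant mice gave 0 and genotype by time 1582.

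Without 5 libraries, SD in mutant mice gave 0, with 17 and with 14 libraries and index sets too, and the correlation of the SD response in both genotypes was 0.0282 over all genes. Over the 39 chaperone, glucocorticoid-responsive and cold-inducible genes that correlation was 0.878 without 5 libraries, with 37 of the same sign. These lists were not singled out in advance and had moved alike in both genotypes, so it is no separate evidence of a shared response. Genotype after SD gave 3 with 17 libraries and index sets and 1 with 14, and SD in control mice 4 with 14. Limma-voom with 17 libraries gave 31 for genotype after SD, 73 for SD in control mice, and 3 each for SD in mutant mice and genotype by SD. With 14 it gave 3 for SD in control mice and 0 for genotype after SD, SD in mutant mice and genotype by SD. DESeq2 with 17 gave 92 for genotype at ZT6, 220 for genotype after SD, 229 for SD in control mice, 97 for SD in mutant mice, 89 for genotype by SD and 127 for time in control mice.

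Leaving out 1 library at a time gave 8693 to 9896 calls for genotype at ZT0, 0 to 1356 at ZT6, 0 to 0 after SD and 7659 to 9504 over the 3 states. It gave 0 to 1 for SD in control mice, genotype by SD and time in control mice, 0 to 1231 for SD in mutant mice, 3454 to 10207 for time in mutant mice and 2340 to 8530 for genotype by time.

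With 22 libraries, over all comparisons, camera made 109 list calls at its preset, 0 with an estimated correlation, and fry made 34. Camera tests a list against the other genes, so its direction can turn while the median keeps its sign. In the 17-library fit it turned for these lists, none with an estimated-correlation call; the medians are given, and those of astrocyte at ZT6, of myelin and blood for SD in mutant mice and of pituitary kept their sign. For genotype at ZT6 immediate early (−0.0762), neuropeptides (0.0611), receptors (0.0904), prohormone processing (0.20), transmitter (0.0147), transcription factors (0.15), glucocorticoid-responsive (−0.23), ribosomal (−0.31), myelin (0.13) and astrocyte (−0.0309). For SD in mutant mice neuropeptides (−0.0781), transcription factors (−0.19), myelin (0.0323) and blood (0.0244). For genotype by SD immediate early (0.00303), neuropeptides (−0.27), receptors (−0.18), prohormone processing (−0.0901), transmitter (−0.16), myelin (−0.30) and astrocyte (−0.14), and for time in control mice pituitary (0.43).

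Leaving out 1 library at a time gave these medians, lowest to highest, for lists whose camera direction turned. Ranges on 1 side of 0 are those of lists whose median kept its sign. Genotype at ZT6: immediate early −0.15 to 1.60, neuropeptides −1.01 to 0.0317, receptors −0.94 to 0.0273, prohormone processing −0.89 to 0.0960, transmitter −1.10 to −0.0849, transcription factors −0.68 to 0.14, glucocorticoid-responsive −0.11 to 1.85, ribosomal −0.42 to 0.85, myelin −0.97 to 0.0412 and blood −0.90 to 0.48. Genotype after SD: pituitary 1.02 to 6.17. SD in control mice: OXPHOS −0.16 to 0.44. SD in mutant mice: immediate early −1.92 to 0.0772, neuropeptides −0.0696 to 0.97, transcription factors −0.11 to 0.85, myelin 0.15 to 1.14, microglia 0.0419 to 0.69 and blood −0.58 to 1.20. Genotype by SD: neuropeptides −0.19 to 0.84, receptors −0.11 to 0.93, prohormone processing 0.12 to 1.03, transmitter 0.0256 to 1.01, myelin −0.17 to 0.83 and astrocyte −0.11 to 0.83. Most changes came without mutant ZT6 replicate 3.

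For named genes, 15520 alternative values of 751 gene and comparison pairs were computed: 14460 kept direction and side of the threshold, 157 passed where the reported value did not, 856 no longer passed and 47 changed sign. Nearly all of the 47 belong to SD in mutant mice. With 3 runs of index numbers they were Ptgs2 0.76, Adm 0.25, Hoxc6 2.38, Ccl2 0.61, Ccl7 1.18, H19 0.66, Plac8 7.04, Hoxd8 1.24 and Thbs1 1.17. Without 5 libraries they were Adm 0.42, Plac8 1.65 and Thbs1 0.20, and with index sets Adm 0.39, H19 0.38, Plac8 1.87 and Thbs1 0.77. Without 8 they were Ptgs2 0.65, Adm 0.41, H19 0.42, Plac8 1.56 and Thbs1 0.70. Limma-voom gave Adm 0.27, Ccl7 0.0901, Plac8 2.15 and Thbs1 0.71 with 17, and Ptgs2 0.80, Adm 0.44, H19 0.43, Plac8 2.24 and Thbs1 0.83 with 14. DESeq2 with 17 gave Adm 0.44, Serpinb9b 1.77, H19 0.42, Plac8 1.94, Hoxd8 0.63, Thbs1 0.81, Plin4 2.96 and Fosl2 1.08. Leaving out 1 library at a time gave Adm −6.22 to 0.46, Serpinb9b −12.39 to 2.71, Plac8 −9.75 to 1.62, Hoxd8 −10.31 to 1.46 and Thbs1 −9.41 to 0.25, each highest without mutant ZT6 replicate 3. The others came from leaving out mutant ZT0 replicate 2, with Xist at −0.15 to 8.05 at ZT0 and −0.22 to 2.51 over the 3 states and Gbp2b at −8.59 to 0.47 in genotype by time, and mutant ZT0 replicate 1, with Rps12l1 as low as −6.37 at ZT0.

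The median log2 change of all genes, against which fold changes are to be read, depended on the scaling: for genotype at ZT6 −0.0977 with TMM, −0.151 with RLE and 0.194 with DESeq2, over the 3 states −0.131 with TMM and 0.378 with DESeq2, for SD in mutant mice 0.0484 and −0.323; for time in mutant mice 0.166 with TMM and −0.105 with RLE; for genotype by time 0.116 with TMM, −0.151 with RLE and 0.507 with DESeq2.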

Other observations

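The genes in this part were named, and the limma-voom and 17-library fits chosen, after their values were seen. Limma-voom with 17 libraries and index sets (n = 4 each) called 38 genes up and 35 down after SD in control mice, and 6 of 35 splits of these libraries, the real one included, called 73 or more, up to 1409. With 14 libraries limma-voom called 3 genes, and edgeR with 17 called 0. Glutamine synthetase (Glul) rose by 0.65 log2 (adjusted p = 0.00217), the nuclear paraspeckle protein gene Sfpq by 0.65, the small GTPase gene Arl4d by 1.67 and the transcriptional repressor gene Bcl6 by 0.67. The co-chaperone genes Stip1 (+0.62), Ahsa1 (+0.52) and Fkbp4 (+0.47) and the chaperone Hsp90ab1 (+0.40) rose, and so did the secreted peptide precursor Vgf (+0.83) and the lipid transporter Mfsd2a (+0.98). The taurine transporter Slc6a6 fell by 0.67, the lipid regulator Srebf1 by 0.43, the imprinted Mest by 1.72, and Tgfbi by 1.28. In edgeR with 22 libraries Arl4d was at +1.70, Mest at −1.41 and Srebf1 at −0.16 (adjusted p = 1 for each).

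Some genes passed over their list alone in the 17-library fit and none of them over all genes. Between ZT0 and ZT6 in control mice, the metallothionein Mt1 was at +1.46 ± 0.38 (SE, n = 3 and 4), the respiratory chain gene Ndufa9 at +2.34 ± 0.45, Egr1 at +0.58 ± 0.16, the oligodendrocyte precursor receptor Gpr17 at −0.73 ± 0.15, Col1a1 at −2.48 ± 0.81 and Col3a1 at −2.33 ± 0.70. In mutant against control mice after SD (n = 4 each), Egr1 was at −0.59 ± 0.14, the prohormone convertase Pcsk2 at +0.49 ± 0.13, the sterol gene Msmo1 at −0.43 ± 0.12, mt-Co2 at −1.12 ± 0.27 and mt-Nd3 at −0.76 ± 0.23. After SD in mutant mice (n = 2 and 4) Fosl2 was at +1.04 ± 0.27, Egr1 at −0.56 ± 0.16 and the myelin gene Opalin at −1.17 ± 0.26. After SD in control mice (n = 4 each) the pericyte gene Pdgfrb was at −0.53 and Prkcd at +0.62.

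Over the same 6 h in control mice, 5 more lists were called by camera in the 17-library fit. Neuropeptides were higher for 25 of 32 (median 0.34) and microglia for 9 of 10 (0.38), and endothelium and pericytes were lower for 7 of 10 (−0.20), meninges and fibroblasts for 7 of 9 (−0.74) and chaperones for 14 of 21 (−0.21). With an estimated correlation the adjusted p was 0.547 for neuropeptides and endothelium and 0.61 for the other 3. Each call was lost without at least 1 library: without control ZT6 replicate 2 neuropeptides were at 0.06 and microglia at 0.03, without control ZT0 replicate 2 endothelium and pericytes at −0.02 and meninges and fibroblasts at −0.16, and without control ZT6 replicate 3 chaperones at 0.03.

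Mutant ZT0 replicate 2 differs from the other 3 libraries with few neural transcripts. Xist stands at 1114 CPM in it and at 0 to 2.802 in the 21 others. The Y-linked genes are near 0, with Eif2s3y at 0, Uty at 0.4833, Ddx3y at 0.5712 and Kdm5d at 2.153 CPM. Genes picked for being high in the same library are Mmp3 at 10740 CPM, Saa3 at 9982, Ccl2 at 4189, Lcn2 at 2553, Ccl5 at 1878, Nos2 at 412.8 and Cybb at 192.4. In mutant ZT0 replicates 1 and 3 and mutant ZT6 replicate 3, Nos2 is at 0, 0.3816 and 0, Saa3 at 1.904, 6.106 and 4.265, and Lcn2 at 4.284, 21.37 and 21.33. The labels give no sex.

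Ube3a counts differed by index set and, within sets 1 and 3, were higher in the mutant libraries. They were 0 in all other libraries of set 2 than the 4 with few neural transcripts, and 102, 1306, 188 and 826 in the 4 libraries of set 3 (control ZT6, mutant ZT6, control SD and mutant SD replicate 4), or 7.037, 48.68, 9.298 and 46.59 CPM. Set 1 had 0, 0, 51 and 875 (control ZT6 replicate 1, control SD replicates 1 and 2, mutant SD replicate 1). Those 4 had 259, 25 and 28 (mutant ZT0 replicates 1 to 3) and 692 (mutant ZT6 replicate 3).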
